A study of Mus musculus with 13 samples.

How the data were processed

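RNA of 6 Ptch1 medulloblastomas, 3 samples of granule neuron precursor cells at postnatal day 7 (GNPC) and 4 samples of dorsal brainstem at E16.5 (DBS) was hybridised to Affymetrix mouse arrays with 45101 probe sets, 1 array per sample. Per the labels' protocols, labelled RNA was made from total RNA by the manufacturer's 2-cycle amplification, and every sample came from a different mouse. The deposited values are linear intensities from MAS5, which is named in the submitters' processing notes with no role or version. In the files, each array has a mean of 500 after trimming 2% of values at each end, so the authors' scaling is global and involves no log or quantile step. Values run from 0.1 to 37660.4, and array medians from 91.3 to 117.5. MAS5 detection calls were not used here.

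Groups were taken from the labels' source names. Replicate numbers follow accession order and pair nothing. The labels give no batch, scan day, litter, sex, strain or age of the tumour mice, so batch and group cannot be told apart. In the normal samples age goes with tissue. A Ctnnb1 tumour group that the series describes was not analysed here.

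Of 45037 probe sets that are not controls, 34945 have 1 gene symbol, 932 have several and 9160 have none in the platform annotation. Symbols were checked against a current gene table through gene identifiers, and 0 changed. The symbols cover 18193 genes. Analyses of genes used probe sets with 1 symbol that exceeded their own array's median in at least 3 of 13 arrays, and, for each gene, the probe set with the highest mean, which left 12270 genes. Of these, 5612 had more than 1 probe set past the filter. A called gene had another probe set called in the opposite direction in 5 cases between tumours and GNPC, 41 between tumours and DBS, and 17 between GNPC and DBS.

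Values were tested as log2(value + 18), 18 being the 20th percentile of all values. Dim genes have their fold understated on this scale. One limma model with a mean per group was fitted to all 13 samples (lmFit, and eBayes with an intensity trend, 10 residual and 4.5 prior degrees of freedom), and the 3 differences between groups were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with a log2 difference of at least 1. Data were simulated with the real genes, each gene's mean over all samples and 1 moderated spread per gene, the same in every group. Genes were drawn independently, so unequal spreads between groups and correlated genes were not covered. Between tumours and GNPC, changes of 1.5, 2 and 3 on the log2 scale were recovered at 87.9%, 95.5% and 100%. There were 8 false calls among the unchanged genes of 12270. The shares were 95.5%, 98.5% and 98.5% between tumours and DBS, with 3 false calls, and 89.4%, 98.5% and 100% between GNPC and DBS, with 4.

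Genes above or below both normal tissues were those called in both tumour comparisons in the same direction. Since these share the tumour arrays, the number was set beside the overlap of independent lists, beside 20 simulations with unchanged groups, and beside 20 splits in which each comparison used a different 3 tumours. Similarity was the mean Pearson correlation across genes of the tumours with GNPC minus that with DBS, tested by an exact two-sided permutation over the 35 relabellings of the normal samples. Position was the projection of a sample on the line from the DBS mean to the GNPC mean, over genes called in a fit on the normal samples alone, with each normal sample placed by genes and means chosen without it. RNA quality was the log2 ratio of 3' to 5' probe sets of Gapdh and beta-actin, compared by exact permutation.

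Before the data were examined, 14 lists of pathway and identity genes and 11 lists of cell type markers were fixed. The former were hedgehog pathway and targets, Wnt targets, granule neuron precursor, differentiated granule neuron, Hox genes, midbrain and anterior hindbrain, dorsal hindbrain and rhombic lip, cell cycle, pan-neuronal maturation, stem cell and radial glia, growth control and p53, interferon and MHC class I, immediate early and heat shock, and hypoxia and glycolysis. The marker lists were astrocytes and Bergmann glia, oligodendrocytes, microglia and macrophages, endothelium, pericytes, meninges and fibroblasts, choroid plexus, blood, Purkinje cells, brainstem transmitter and identity genes, and cerebellar interneurons. Some genes are in more than 1 list. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, then with an estimated correlation, and with directional fry, adjusted over the 25 lists of a comparison. Camera asks whether a list moved against the other genes, and fry whether its members moved on balance in 1 direction. Camera at the preset passed 13, 10 and 9 lists in the comparisons of tumours with GNPC, tumours with DBS and GNPC with DBS. With an estimated correlation 0, 3 and 3 lists passed, and fry passed 21, 17 and 14.

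Genes named in the text follow a rule fixed at the same time. It takes the 6 largest changes in each direction per comparison among called genes without overlap between groups, the 4 members of each list with the largest change, the 6 genes farthest from both normal tissues in each direction, and Ptch1, Gli1, Hhip, Atoh1, Zic1, Barhl1, Mycn, Ccnd1, Mki67, Hoxb4, En2 and Olig3. It passes over predicted genes and takes up genes with an outlying sample. Some genes that the rule takes are not reported here.

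Alternatives were a pseudocount of 1 or of the median of all values, quantile normalization, scaling to the same median, no filter or a 70th percentile filter, other variance models, the mean of probe sets, no cross-hybridising probe sets, all probe sets, only the compared groups in the fit, a per-gene unequal-variance test, no minimum fold, and each of the 13 samples left out. The similarity and position were also computed with other measures and gene sets. After the data were seen, 2 alternatives were added: tumour 2 and GNPC 1 left out together, and presence of the Y-linked transcript Eif2s3y as a covariate. The versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Genome positions are not given, since no build is named for the probe sets in the sources used here.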

Results

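Gene expression was measured in 13 mouse samples on 1 array each, every sample from a different mouse. Of these, 6 were primary medulloblastomas, malignant tumours of the hindbrain, from mice with 1 inactivated copy of Ptch1. Ptch1 encodes the receptor that holds the hedgehog pathway in check until a hedgehog ligand binds. The other samples were normal tissue of wild-type mice: 3 of cerebellar granule neuron precursor cells at postnatal day 7 (GNPC), and 4 of dorsal brainstem at E16.5, late in gestation (DBS). Granule neuron precursors divide in the outer layer of the young cerebellum in response to Sonic hedgehog. The comparisons asked how the tumours differed from each normal tissue and which of the 2 they resembled. A tumour group with a Ctnnb1 alteration that the series also describes was not analysed here. Array medians lay between 91.3 and 117.5 intensity units, and the number of arrays limits the precision of every value.

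Ptch1, the targeted gene, was measured in every sample by a probe set whose intensity in tumours 1 to 6 was 7986.5, 3453.7, 7275.5, 9694.4, 6620.5 and 11575. It was 5563.3, 6309.3 and 6972.4 in GNPC 1 to 3, and 5569.3, 6133.5, 5890.2 and 5915.8 in DBS 1 to 4. Ptch1 passed the test in none of the 3 comparisons (tumours against GNPC, log2 difference 0.22 ± 0.26 SE, limma adjusted p = 0.509). The sources used here do not state which part of the gene is deleted, so this probe set checks nothing about the labels.

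Against the GNPC samples, the tumours had more RNA of hedgehog targets, of the cell cycle and of macrophage markers. They had less of differentiated neurons, meninges and other cerebellar cell types, by gene list tests at a preset correlation between genes. Markers of other cerebellar cells were abundant in the GNPC samples, so changes in both directions may reflect the mix of cells. With an estimated correlation, 0 of the 25 lists passed in this comparison. Gli1, the transcription factor and target of the hedgehog pathway, was 5.94-fold higher (821 ± 82.4, SD, n = 6, against 123 ± 8.76, SD, n = 3; limma adjusted p = 3.32e-07). Atoh1, the transcription factor that marks granule neuron precursors, was 8.07-fold higher (8637 ± 1944 against 1048 ± 214; adjusted p = 6.52e-07). Nefl, the neurofilament light chain, was 22.4-fold lower (283 ± 247.5 against 5048 ± 414; adjusted p = 1.01e-05). Folds are on the log2(value + 18) scale, which understates the change of dim genes.

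Of 12270 genes tested, 2552 (20.8%) passed, 809 higher and 1743 lower in tumours. With every array scaled to the same median, 2684 passed and the split was 1309 higher to 1375 lower, so the share of higher calls went from 31.7% to 48.8%. That scaling moved the median gene from -0.03 to 0.21 on the log2 scale, so directions of small changes in this comparison are relative to the scaling. At least 8-fold changes numbered 31 upward and 119 downward. The values of the 2 groups did not overlap for 2336 of the called genes; over all genes they did not overlap for 44.9%, where chance gives 2.38%.

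Of the 22 measured hedgehog pathway genes and targets, 9 rose, 4 fell and 9 did not pass (camera adjusted p = 0.0011, and adjusted p = 0.11 with an estimated correlation). Cdk6, a kinase that drives entry into S phase, rose by 3.39 on the log2 scale, from 897 ± 192 to 9652 ± 2100. Its partner Ccnd1 rose by 2.07, the pathway antagonist Hhip by 2.05 and the co-receptor Boc by 1.98. Shh, the ligand, was 5.05-fold lower in tumours (101 ± 43.8 against 566 ± 157). In this and every list of this comparison the number of members passing was the same when adjusted over the list alone, except where stated.

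Of 39 measured cell-cycle genes, 30 rose, none fell and 9 did not pass (camera adjusted p = 2.4e-16, and adjusted p = 0.21 with an estimated correlation). The replication licensing factors Mcm2 and Cdc6 rose by 2.09 and 1.9 on the log2 scale. Mki67, the proliferation antigen, rose by 1.04, from 6112 ± 1282 to 12410 ± 1276, and without GNPC 1 its difference of 0.86 no longer passed the 2-fold minimum. Hmgb2, a chromatin protein of dividing cells, rose by 1.06 and also lost its call without GNPC 1 (0.72).

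Of 19 measured genes of the granule neuron precursor state, 5 rose, 2 fell and 12 did not pass. The list did not pass against the other genes (median log2 difference 0.21, camera adjusted p = 0.22), but it passed the test of whether its members moved on balance in 1 direction (fry adjusted p = 0.0074). Sfrp1 rose by 1.54 and Atoh1 by 3.01, while Eomes, a T-box factor of unipolar brush cells, was 11.3-fold lower and Mfap4, a microfibril-associated protein, 3.97-fold lower. Zic1 had the same level in both (19700 ± 1365 and 20140 ± 546; log2 difference -0.03 ± 0.09 SE) and Pax6 a difference of -0.64 that did not pass. Barhl1 and Insm1 stood at 0.98 and 0.96, just short of the 2-fold minimum, and passed it with arrays scaled to the same median (1.23 and 1.2).

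Of 16 genes of differentiated granule neurons, 10 fell, none rose and 6 did not pass (11 passed when adjusted over the list alone; camera adjusted p = 0.002, and adjusted p = 0.39 with an estimated correlation). The netrin receptor Unc5c was 9-fold lower and the transcription factor Neurod2 6.49-fold lower. Gabra6, the GABA-A receptor subunit of mature granule cells, was 8.85-fold lower, but it ranged from 6.8 in tumour 1 to 4620.9 in tumour 2, and its call was lost without any 1 of the GNPC samples (adjusted p = 0.0625 to 0.0773). Of 24 pan-neuronal genes, 14 fell, none rose and 10 did not pass (camera adjusted p = 2.2e-08, and adjusted p = 0.26 with an estimated correlation). Besides Nefl, these included the neurofilament Nefm (13.4-fold lower) and the synaptic vesicle protein Syt1 (8.22-fold lower).

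Many markers of other cerebellar cells were abundant in the GNPC samples and lower in the tumours. The labels do not say whether the GNPC samples were purified cells or whole cerebellum. The mean of the Purkinje list was 11.01, 10.63 and 10.83 on the log2 scale in GNPC 1 to 3, and at most 9.81 in a tumour. These values argue against GNPC samples of precursors alone. Falls against the GNPC samples may therefore reflect the mix of cells, and so may rises of hedgehog, precursor and cell-cycle genes. Of 16 Purkinje cell genes, 11 fell and none rose (camera adjusted p = 0.0011, and adjusted p = 0.39 with an estimated correlation); the calcium buffer Calb1 went from 14500 ± 1447 in GNPC to 1091 ± 1396 in tumours, and the glutamate transporter Slc1a6 was 30.1-fold lower. Of 11 cerebellar interneuron genes, 7 fell and 1 rose (0.0026, and adjusted p = 0.37 with an estimated correlation), among them the vesicular GABA transporter Slc32a1, 23.1-fold lower, and the GABA-synthesizing enzyme Gad1, 14.5-fold lower. Of 21 brainstem transmitter and identity genes, which include Slc32a1 and Gad1, 8 fell and 1 rose (0.019, and adjusted p = 0.39 with an estimated correlation). Of 23 astrocyte and Bergmann glia genes, 10 fell and 2 rose (0.028, and adjusted p = 0.47 with an estimated correlation); Gdf10, a Bergmann glia marker, was 20.3-fold lower. Of 16 oligodendrocyte genes, 8 fell and none rose, with the list not passing by camera (adjusted p = 0.076) and passing by fry (0.0093); the myelin genes Mag and Mobp were 11.6-fold and 8.42-fold lower, and Mbp was 17680 ± 4287 in GNPC.

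Of 20 genes of meninges and fibroblasts, 13 fell and none rose (camera adjusted p = 9.1e-05, and adjusted p = 0.11 with an estimated correlation), among them the collagen chain Col1a2, 8.45-fold lower, and the matrix proteoglycan Ogn, 10.4-fold lower. Of 19 endothelial genes, 8 fell and 2 rose (0.03, and adjusted p = 0.47 with an estimated correlation; 0.054 without tumour 2). The VEGF receptor Kdr was 4.49-fold lower, while Sox18, a transcription factor of endothelium, was 11.2-fold higher (3356 ± 244 against 290 ± 80.3). Of 26 microglia and macrophage genes, 14 rose and 1 fell (9.1e-05, and adjusted p = 0.44 with an estimated correlation). The MHC class II chain H2-Aa was 8.66-fold higher and the lysosomal protein Cd68 3.65-fold higher. The lysozymes Lyz1 and Lyz2 were 20.1-fold and 16.6-fold higher, though these near-identical paralogs are uncertain as separate measurements.

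Of 18 interferon and MHC class I genes, 6 rose and none fell (camera adjusted p = 0.019, and adjusted p = 0.47 with an estimated correlation), but without tumour 2 the adjusted p was 0.054. The interferon-induced gene Ifit3 was 3583 in tumour 2 and between 164.6 and 353.7 in the other tumours. Of 19 growth control and p53 genes, 5 rose and 2 fell (0.021, and adjusted p = 0.39 with an estimated correlation). The p53 target Eda2r was 7.39-fold higher. The cyclin kinase inhibitor Cdkn2b was 7.06-fold higher, and Cdkn1b, an inhibitor of another family, 2.84-fold higher.

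The remaining lists did not pass against GNPC by camera. By fry all of them except the Hox, stem cell and choroid plexus lists passed (adjusted p from 9.8e-06 for dorsal hindbrain genes to 0.013 for pericytes). None of 13 Hox genes passed (median log2 difference 0.04, mean -0.05). Of 12 dorsal hindbrain and rhombic lip genes, 3 rose and 6 fell (camera adjusted p = 0.41): the sensory neuron factor Pou4f1 was 10.7-fold higher and the proneural factors Neurog2 and Ptf1a 8.81-fold and 6.44-fold lower. Of 8 midbrain and anterior hindbrain genes, 3 fell (0.086), with En2, a cerebellar homeobox gene, down by 1.05 to 1507 ± 185; without GNPC 1 its difference was -0.96, without tumour 1 -0.99, and with arrays scaled to the same median -0.8, each short of the 2-fold minimum. Of 18 stem cell and radial glia genes, 2 rose and 5 fell (0.64), with Sox1 3.62-fold higher and Id4 14-fold lower. Of 23 hypoxia and glycolysis genes, 1 rose and 5 fell (0.069): hexokinase Hk2 was 11.1-fold higher and its relative Hk1 3.66-fold lower. Of 14 Wnt targets, 1 rose and 4 fell (0.24), and the list's median of -0.18 became 0.05 with arrays scaled to the same median. Of 24 immediate early and heat shock genes, 2 rose and 2 fell (0.22), with Fosl2 5.64-fold higher and Hspa1b 4.26-fold lower. Of 10 pericyte genes 5 fell (0.14), of 5 blood genes 2 fell (0.23), and of 13 choroid plexus genes 1 fell and none passed when adjusted over the list alone (0.41).

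The largest rise over GNPC among named genes was that of Prm1, a sperm nuclear protein gene, with intensities of 1138.6 to 3326.1 in the 6 tumours and at most 4.2 in the normal samples; 10 other spermatid genes had a median log2 difference of 0.03 between tumours and normal samples. Lcn2, an iron-carrier binding protein of inflammation, was 38-fold higher, ranging from 64.2 to 3959.3 across tumours. It was at background in GNPC (4.27 ± 2.27), so this fold depends on the pseudocount. Mroh2a was 30.8-fold higher (226 to 7670.3), and Tbata, named for its expression in brain, thymus and testis, 22.7-fold higher at 3620 ± 436. The probe sets of Prm1, Tbata, Lyz1 and H2-Aa are of the kind left out in the setting with no cross-hybridising probe sets. Binding of other transcripts to them was not tested. Other falls of at least 8-fold included Arhgef33 (21.5-fold), Pcp2 (20.9-fold) and Aldh1l1 (11.4-fold), genes of Purkinje cells and astrocytes.

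The ratio of 3' to 5' signal of the control transcripts, a sign of RNA quality, was higher in tumours than in GNPC, with a mean log2 of 1.39 ± 0.0984 (SD, n = 6) against 1.16 ± 0.0454 (SD, n = 3). The difference of 0.23 had an exact two-sided permutation p of 0.0119, the smallest this design allows (0.0357 after Benjamini-Hochberg adjustment over 3 comparisons). With the Gapdh control alone it was 0.17 (exact permutation p = 0.179). No batch label was given, so batch and tissue cannot be told apart in any comparison.

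**Figure D1:**
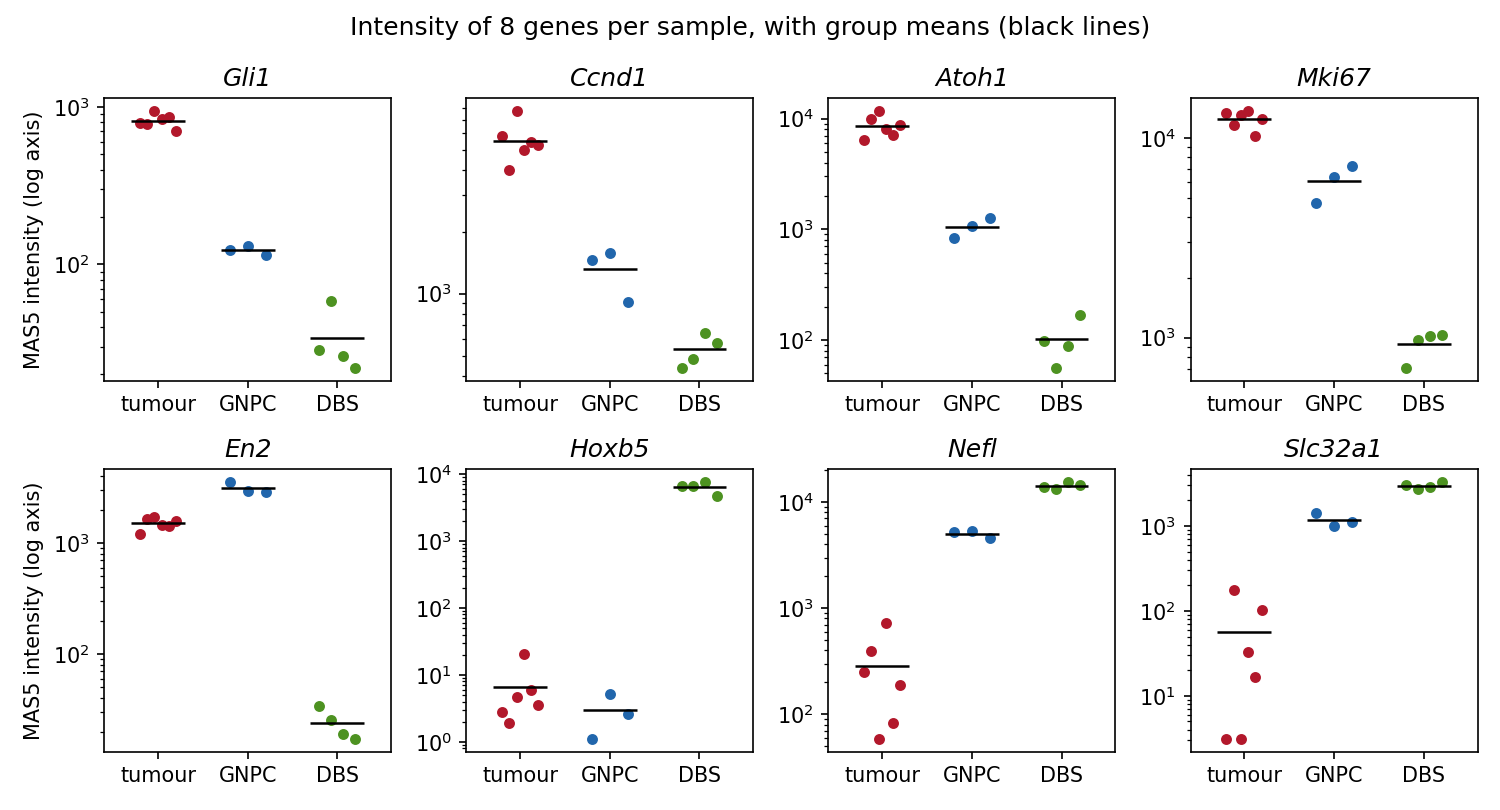
MAS5 intensity on a log axis of 8 genes in each sample (points: 6 tumours, 3 GNPC, 4 DBS; black lines: group means). Gli1, Ccnd1, Atoh1 and Mki67 were highest in tumours, En2 averaged 23.8 in DBS, 3125 in GNPC and 1507 in tumours, Hoxb5 averaged 6387 in DBS and 6.62 in tumours, and Nefl and Slc32a1 were lowest in tumours.

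Against dorsal brainstem, the tumours had little RNA of the Hox genes and the transmitter genes of brainstem neurons and more RNA of granule neuron precursors and of the cell cycle. With an estimated correlation between genes the Hox and precursor lists passed, and the transmitter and cell-cycle lists did not (adjusted p = 0.082 for each). Hoxa5, which patterns the posterior hindbrain, stood at 7239 ± 1286 (SD, n = 4) in DBS and 8.43 ± 5.32 (SD, n = 6) in tumours, 275.6-fold lower (limma adjusted p = 1.17e-12). Atoh1 was 74.6-fold higher in tumours (102 ± 46.5 in DBS; adjusted p = 2.15e-11). En2 was 36.7-fold higher, at 23.8 ± 7.63 in DBS (adjusted p = 1.79e-12). Slc6a5, the glycine transporter of inhibitory brainstem neurons, was 96.1-fold lower (3330 ± 365 in DBS against 22.3 ± 27.2; adjusted p = 3.89e-10).

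Of the 12270 genes, 4457 (36.3%) passed, 1896 higher and 2561 lower in tumours, with 230 and 458 changed at least 8-fold. The groups did not overlap for 4211 of the called genes and for 56.1% of all genes, where chance gives 0.95%. Scaling to the same median moved the median gene by 0.12, from 0, and the split was then 2234 higher to 2351 lower.

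All 13 measured Hox genes fell (camera adjusted p = 6.5e-08, and adjusted p = 0.018 with an estimated correlation). Hoxb5 was 263.3-fold, Hoxc4 249.9-fold, Hoxb3 109.6-fold, Hoxc5 63.8-fold and Hoxb4 18.1-fold lower, with tumour values near background, so that these folds and that of Hoxa5 depend on the pseudocount. Of 21 brainstem transmitter and identity genes, 20 fell and 1 rose (1.5e-06, and adjusted p = 0.082 with an estimated correlation). Besides Slc6a5, the neuropeptide gene Tac1 was 56.7-fold lower and the intermediate filament Prph 42.6-fold lower. Prph was near background in tumours (12 ± 10.8), so its fold also depends on the pseudocount. Of 24 pan-neuronal genes, 20 fell and none rose (6.5e-08, and adjusted p = 0.2 with an estimated correlation); Nefl was 63.2-fold lower, Nefm 53.5-fold, Syt1 15.8-fold and the microtubule protein Map2 5.80-fold lower, though with the mean of probe sets Map2 differed by -0.87 on the log2 scale, short of the 2-fold minimum. Of 11 interneuron genes, 8 fell and 2 rose (0.012, and adjusted p = 0.38 with an estimated correlation), Slc32a1 by 58.4-fold. Of 23 hypoxia and glycolysis genes, 14 fell and 2 rose (0.0019, and adjusted p = 0.38 with an estimated correlation): phosphofructokinase Pfkp was 12.2-fold and Pdk1 7.76-fold lower while Hk2 was 18.7-fold higher. In this comparison the number of members passing was the same when adjusted over the list alone for every list except oligodendrocytes (3 over all genes, 2 over the list).

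Of 22 hedgehog genes and targets, 13 rose and 2 fell (camera adjusted p = 0.00028, and adjusted p = 0.049 with an estimated correlation). Gli1 was 16.7-fold higher (33.8 ± 16.7 in DBS), Cdk6 18.9-fold, Sfrp1 12.3-fold and Boc 11.8-fold higher, while Shh was 6.61-fold lower. Of 19 granule neuron precursor genes, 14 rose and none fell (1.1e-07, and adjusted p = 0.041 with an estimated correlation): Insm1 was 44.3-fold, Barhl1 14.6-fold, Mfap4 14.5-fold and Pax6 9.61-fold higher. Zic1 differed by 0.37, under the 2-fold minimum. Of 39 cell-cycle genes, 38 rose and none fell (1e-19, and adjusted p = 0.082 with an estimated correlation); the mitotic checkpoint kinase Bub1b was 24.7-fold, E2f1 21.8-fold, Cdc6 16.8-fold and Mki67 13.2-fold higher.

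Of 26 macrophage genes, 16 rose and none fell (camera adjusted p = 0.00028, and adjusted p = 0.63 with an estimated correlation), with Cd68 9.41-fold and H2-Aa 7.97-fold higher. Of 18 interferon genes, 8 rose (0.037, and adjusted p = 0.81 with an estimated correlation), but the adjusted p was 0.062 without tumour 2, 0.051 without tumour 6 and 0.059 without DBS 2. The other lists did not pass by camera; by fry those of differentiated granule neurons, dorsal hindbrain, growth control, astrocytes, pericytes, meninges and blood passed (adjusted p from 1.3e-05 to 0.04). Members of most of these went both ways; for example, midbrain and anterior hindbrain genes gave 3 higher and 5 lower of 8, with En2, Cnpy1 and Otx2 higher (36.7-fold, 24.2-fold and 9.32-fold) and Lmx1b 13.5-fold lower (list median -1.67, mean -0.02); dorsal hindbrain genes gave 4 and 4 of 12; and differentiated granule neuron genes 7 higher and 3 lower of 16. Olig3, a rhombic lip factor, was 4.61-fold higher on average, but tumours ranged from 21.3 to 1556.2 and its adjusted p of 0.0446 rose to 0.117 without DBS 1. Pcp2 (3.66-fold higher, adjusted p = 0.0475) and Calb1 (4.12-fold lower, 0.0331) also lost their calls without any 1 of the DBS samples.

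Among the largest changes not in a list, Mndal, an interferon-inducible gene, was 75.4-fold higher in tumours (11.2 ± 10.4 in DBS). That DBS value is near background, so the fold depends on the pseudocount. Mndal was at 2185 ± 1199 in GNPC, and at 206.8 in tumour 2. Meis2, a homeobox cofactor, was 156.1-fold lower, the membrane protein Tmem130 117.4-fold lower and Lamp5, a membrane protein of neurons, 93.9-fold lower. The 3' to 5' ratio averaged 1.75 ± 0.497 (SD, n = 4) in DBS, with DBS 2 at 2.43, against 1.39 in tumours (log2 difference -0.36, exact permutation p = 0.0952). With beta-actin alone the difference was -0.51 (exact permutation p = 0.0238). The added poly-A control transcripts were brighter in DBS than in tumours (mean log2 10.5 against 9.35; exact permutation p = 0.0476, 0.0857 after adjustment).

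The normal tissues set the scale for both comparisons. GNPC had more RNA of the cerebellar genes En2, Gabra6 and Pcp2 than DBS and much less of the Hox genes. En2 was 75.8-fold higher in GNPC (3125 ± 353, SD, n = 3, against 23.8 ± 7.63, SD, n = 4; limma adjusted p = 6.07e-12). Gabra6 was 119-fold higher (5517 ± 562 in GNPC) and Pcp2 76.5-fold higher. Hoxb5, Hoxa5 and Hoxc4 averaged 6387, 7239 and 5572 in DBS and 2.97, 7.3 and 12.3 in GNPC, values at background, so no fold is given.

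Of the 12270 genes, 2259 (18.4%) passed, 1071 higher and 1188 lower in GNPC, with 73 and 79 changed at least 8-fold. With every array scaled to the same median the split was 852 higher to 1397 lower, so the share of higher calls went from 47.4% to 37.9%. The groups did not overlap for 2222 of the called genes and for 55.9% of all genes, where chance gives 5.71%. Of 19 granule neuron precursor genes, 16 were higher and none lower (camera adjusted p = 1.6e-11, and adjusted p = 0.0092 with an estimated correlation), with Mfap4 at 5.85, Insm1 at 4.51 and Eomes at 3.92 on the log2 scale. Of 22 hedgehog genes, 10 were higher and none lower (0.00027, and adjusted p = 0.046 with an estimated correlation), among them Ccnd2 (2.69), Sfrp1 (2.08), Gli2 (1.89) and Gli1 (1.49, but 0.72 and no longer called with the pseudocount at the median of all values). Of 13 Hox genes, 12 were lower (2.4e-14, and adjusted p = 0.0014 with an estimated correlation). Of 39 cell-cycle genes, 34 were higher and none lower (1e-23, and adjusted p = 0.056 with an estimated correlation), with Bub1b at 3.47 and Mki67 at 2.68.

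Of 16 differentiated granule neuron genes, 13 were higher in GNPC (camera adjusted p = 4e-06, and adjusted p = 0.19 with an estimated correlation), such as Cbln3 (4.21) and Fat2 (4.14). Of 16 Purkinje cell genes, 10 were higher and 1 lower (0.0046, and adjusted p = 0.51 with an estimated correlation), such as Pvalb (5.08) and Arhgef33 (4.9). Lower in GNPC were 13 of 21 brainstem identity genes (7.1e-07, and adjusted p = 0.056 with an estimated correlation; 14 adjusted over the list alone), including Prph (-4.93), Tac1 (-4.84) and Isl1 (-3.86). Also lower were 11 of 24 pan-neuronal genes (0.00035, and adjusted p = 0.45 with an estimated correlation), such as Nefm (-1.99) and Map2 (-1.9, but -0.48 and no longer called with the mean of probe sets), and 8 of 23 hypoxia and glycolysis genes, with 1 higher (0.002, and adjusted p = 0.41 with an estimated correlation). The other 16 lists did not pass by camera, though by fry the Wnt, midbrain, dorsal hindbrain, immediate early and meningeal lists passed (adjusted p from 1.2e-05 to 0.04). Of the meningeal genes, 7 of 20 were higher in GNPC (6 adjusted over the list alone). The oligodendrocyte list passed by neither test (fry adjusted p = 0.054). Of its 16 genes, 7 were higher in GNPC, such as Mobp (4.23) and Mog (3.5), and 1 was lower. Sex-linked transcripts differed between samples: Eif2s3y of the Y chromosome was 697.7 to 1312.8 in DBS 1 to 3, but 15.5 in DBS 4 and at most 11.5 in the 3 GNPC samples. The 3' to 5' ratio differed by -0.59 (exact permutation p = 0.0571).

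**Figure D2:**
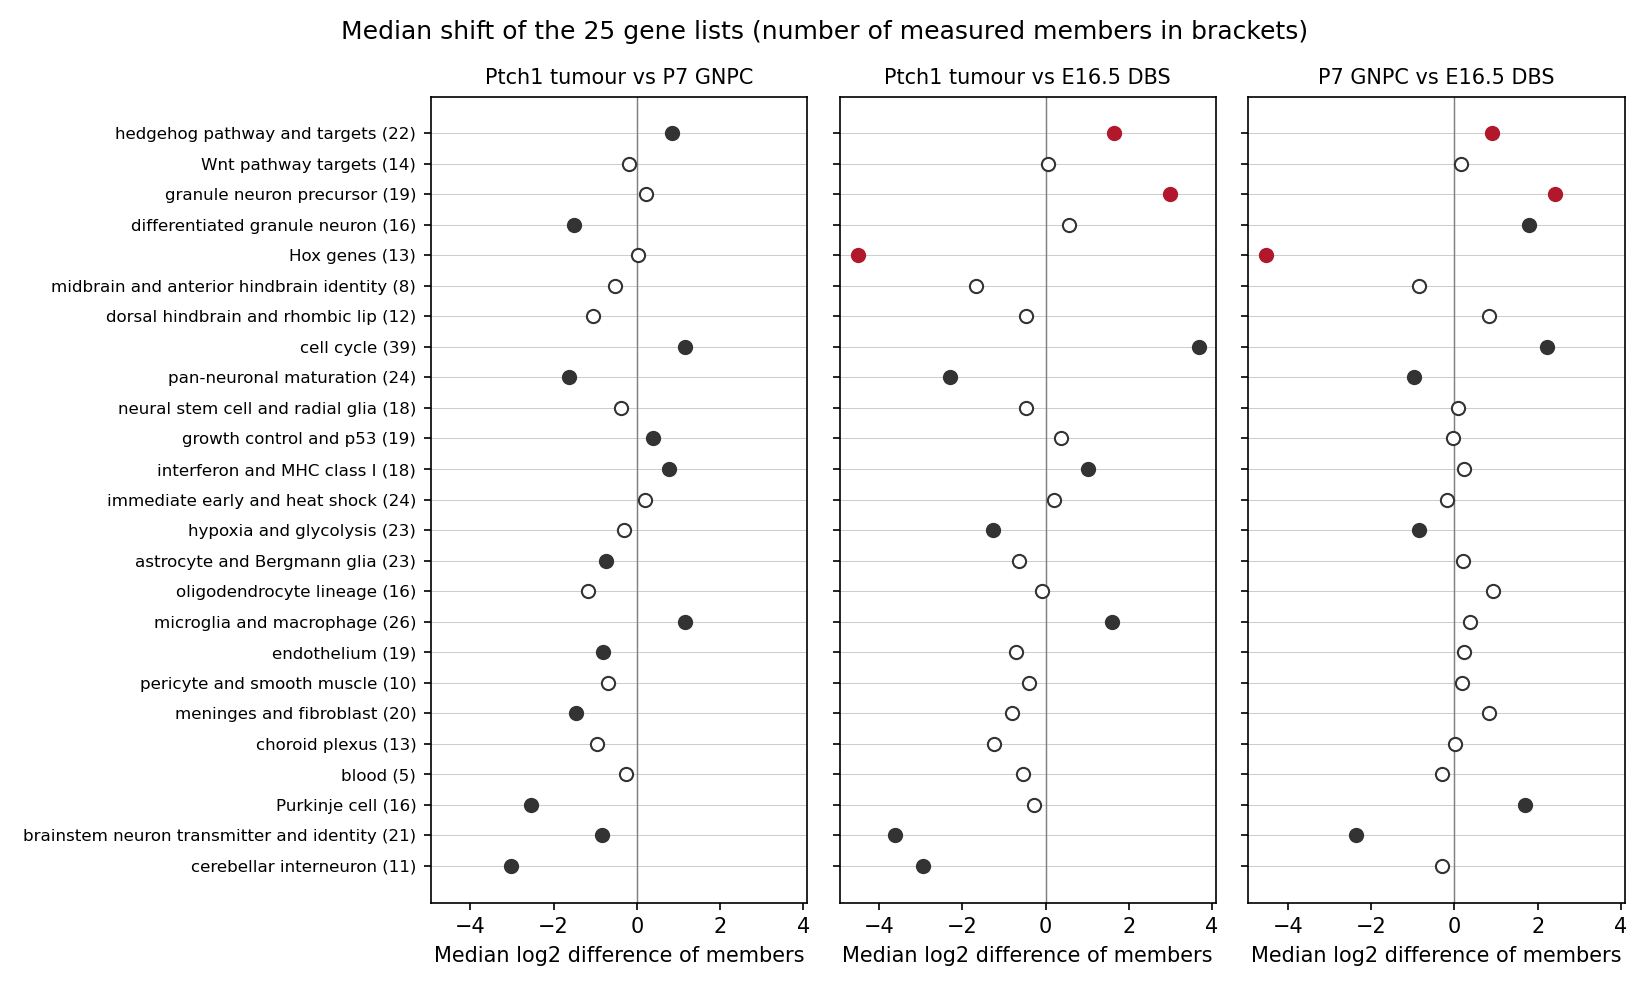
Median log2 difference of the measured members of 25 gene lists in the 3 comparisons (number of members in brackets; filled: camera adjusted p below 0.05; red: also below 0.05 with an estimated correlation). The 3 lists in red, hedgehog, granule neuron precursor and Hox genes, are red in both comparisons with DBS and none is red between tumours and GNPC.

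All 6 tumours resembled the GNPC samples more than dorsal brainstem. Since markers of other cerebellar cells are abundant in the GNPC samples, this does not tell a likeness to precursors from a likeness to cerebellum. The normal tissues also differ in age, postnatal day 7 against E16.5, and the labels give no age for the tumours. A likeness in tissue therefore cannot be told apart from a likeness in age. Across the 12270 genes, which are not independent replicates, the mean Pearson correlation of tumours was 0.862 with GNPC and 0.708 with DBS. The difference of 0.154 was positive in 6 of 6 tumours (0.147 to 0.159). It had an exact two-sided permutation p of 0.0286 over the 35 relabellings of the normal samples, the smallest this design allows. Only normal samples were relabelled, and these already separate by tissue. That p therefore reflects how the normal tissues differ and does not measure the spread among tumours. Tumours correlated with each other at 0.957, GNPC samples at 0.978, DBS samples at 0.976, and GNPC with DBS at 0.859.

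Over 2335 genes that differed between the normal tissues alone, each tumour was placed on a line from the DBS mean (0) to the GNPC mean (1). The tumours lay at 1.15 ± 0.028 (SD, n = 6; 1.11 to 1.18) and were nearer the GNPC mean at 83.7% ± 1.2 of these genes. GNPC samples placed without themselves lay at 0.967 ± 0.135 (SD, n = 3) and DBS samples at 0.027 ± 0.03 (SD, n = 4). Of 1234 genes higher in DBS, such as the Hox genes, 1139 were nearer the GNPC mean in tumours, 470 were lower still than in GNPC and 62 higher. Of 1101 genes higher in GNPC, 829 were nearer the GNPC mean, 233 were lower in tumours than in GNPC and 252 higher.

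**Figure D3:**
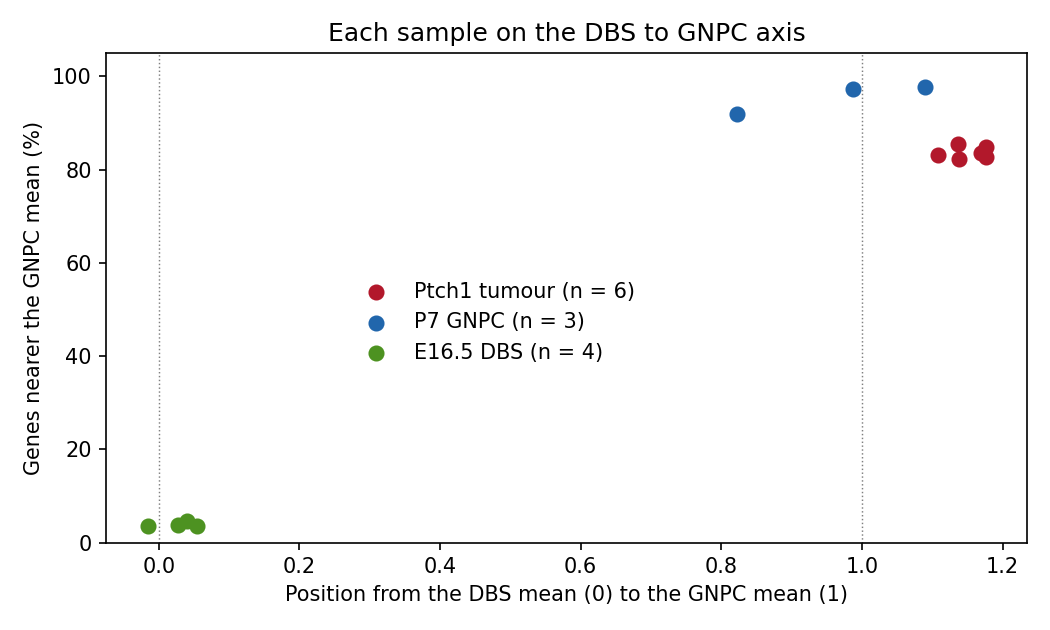
Position of each sample on the line from the DBS mean (0) to the GNPC mean (1), against the percent of genes nearer the GNPC mean. The 6 tumours lie at 1.11 to 1.18 with 82.3% to 85.4% of genes nearer GNPC, to the right of all 3 GNPC samples (0.822 to 1.09).

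Genes that differed from both normal tissues in the same direction numbered 663 higher and 1367 lower in tumours. Independent lists of these sizes would share 125 and 364 genes. In 20 simulations with unchanged groups, at most 0 genes were shared in either direction. Those simulations held no changed gene, so they could not show how far the shared tumour arrays raise the overlap. When the tumours were split so that each comparison used a different 3, the median over 20 splits was 626 higher (562 to 677) and 1309.5 lower (1249 to 1375), against the same 125 and 364 for independent lists. With every array scaled to the same median, the higher genes numbered 1026. Another 4 genes were higher than GNPC and lower than DBS, and 28 were lower than GNPC and higher than DBS.

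The genes farthest above both tissues were Prm1, Lcn2, Mroh2a, Tbata, Lyz1 and Lyz2, with the smaller of the 2 log2 differences 6.73 for Prm1 and 4.05 for Lyz2. Cdk6, Hk2, Sox18, H2-Aa, Atoh1, Eda2r and Gli1 were also above both. Lowest against both were Slc32a1 (-4.53 against GNPC and -5.87 against DBS), Nefl (-4.49 and -5.98), Tmem130 (-4.3 and -6.88), Skor1 (-4.25 and -5.1), Rps4l (-4.24 and -4.98) and Elmod1 (-4.17 and -5.21). Skor1, a corepressor of developing neurons, was highest among the tumours in tumour 6 (2296.4, against 30.6 to 464.9 in the other tumours).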

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

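The tests of Prm1, of tumour 2 and of the sex-linked transcripts of tumour 1 were chosen only after those results were seen, and the choice of genes for the tumour 2 shift was changed after its first result, to pick them for each tumour without that tumour; the counts of other splits of the samples were planned.

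Prm1, whose product packs DNA in sperm, read 1138.6 to 3326.1 in all 6 tumours and at most 4.2 in the 7 normal samples. If tumour cells had switched on spermatid genes, others should have risen with it, but 10 of them had a median log2 difference of 0.03 (-0.31 to 0.5) and none exceeded 60.3 in a tumour, which argues against that explanation. A candidate explanation is a transcript from the engineered Ptch1 allele that ends in Prm1 sequence, since Prm1 3' ends are used in targeting constructs. The construct is not given in the sources used here. The Prm1 probe set is of the kind left out in the setting with no cross-hybridising probe sets, and binding of another transcript was not tested. Prm1 and Ptch1 correlated across the 6 tumours with Pearson r 0.36 (exact permutation p = 0.5) and Spearman rho 0.37 (p = 0.497), and r was 0.81 without the 2 tumours farthest from the median of Ptch1. The other 2 Ptch1 probe sets, dimmer at means of 292.2 and 10.8 in tumours, gave r 0.68 and 0.59 (exact permutation p = 0.114 and 0.158), and adjusted over the 3 relations none passed (0.5, 0.238 and 0.238). This leaves the explanation open, because it is not known which alleles the Ptch1 probe set reads.

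Tumour 2 carried the most RNA of several mature cerebellar genes among the tumours: Gabra6 4620.9, Cbln3 3575.7, Pcp2 1701.9 and Calb1 3812.1, where the other tumours reached 1810.9, 1480.1, 764.9 and 1267.8. These genes ranked the 6 tumours in the same order, which was tumours 1, 3, 4, 5, 6 and 2 from lowest to highest. The differences were therefore graded across the tumours and not confined to tumour 2. Pvalb did not follow, at 3697.4 in tumour 2, 4007.6 in tumour 3 and 3982.3 in tumour 6. A mislabelled normal sample is argued against by Gli1, at 94.3% of the mean of the other tumours. If normal cerebellum were mixed in, the genes that set tumours apart should be diluted, and in tumour 2 the 21 genes at least 8-fold above both normal tissues had a median log2 shift of -1.07, below the -0.35 to 0.24 of the other tumours, as that explanation needs. But this equals 47.8% left, while Gli1 and Atoh1 (117.4%) show no dilution of that size, a comparison added once the shift was known. Other genes above both normal tissues went both ways. In tumour 2, Hk2 was 3601.8 (6342.9 to 10898.4 in the other tumours) and Sfrp1 2281.5 (5057.2 to 8298.6). Sox18 was 3185.4 (3004.3 to 3580.6) and Mycn 9815.8 (8083.6 to 10951.3). Gli1 and Atoh1 therefore do not decide the question. Markers of other cells were also highest in tumour 2: the oligodendrocyte gene Mobp was 1815.8 (at most 711.9 in the other tumours) and the mean of the interneuron list 8.59 on the log2 scale (at most 8.03), though that of the oligodendrocyte list was 9.45, near the 9.34 of tumour 1. Granule cells maturing within the tumour, which was not tested, would not by itself bring these, and a smaller share of cerebellar tissue stays open; 3 of the Purkinje list's genes are also in other lists, and the GNPC samples express these markers too.

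Tumour 1 held both Xist, at 9406.1, and the Y-linked Eif2s3y, at 3003.9, where the other samples held 1 kind only. RNA of a male and a female mixed would give shares of the usual levels that sum to about 1, but the lowest Xist share and lowest Y-linked share of any probe set summed to 1.5, more than that. With Xist taken against its highest sample and the Y-linked share against the usual level, they summed to 1.44. Taken against the highest sample for both, they summed to 1.16, because Kdm5d was 1299.6 in tumour 6 and 703.4 in tumour 1. A mixture therefore stays open. More than 1 X chromosome with a Y chromosome in the same cells would give about 2, and the mean shares summed to 1.72, which does not decide it. Xist itself varied, at 2322.5 in tumour 5 and 9231.3 in tumour 4. The labels give no sex, and no other explanation was tested.

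The real grouping of the samples gave more called genes than every other grouping counted. The other groupings mixed the tissues, which widens the spread within groups and lowers the counts, so chance is not excluded by this. Between tumours and GNPC, 1 of 84 splits, the real one, gave as many as 2552 genes, and the highest other gave 20. Between tumours and DBS, 1 of 100 drawn splits gave as many as 4457, and the highest other gave 2019. Between GNPC and DBS, 1 of 35 splits gave as many as 2259, and the highest other gave 1032. For genes above and below both normal tissues, 1 of 100 drawn groupings each gave as many as 663 and 1367, and the highest others gave 0 and 3.

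Tumours and DBS were checked for a sample far from the rest of its group, and the GNPC samples were not checked. Of 258 values checked, 17 stood out, where chance alone gives about 13 (1 in 20), so single values below carry little weight. In tumour 2, Ifit3 was high at 3583 (others 164.6 to 353.7), Eda2r low at 438 (1209 to 1860) and Mndal low at 206.8 (1982 to 6022). Its mean over the interferon list was 10.14 on the log2 scale (8.02 to 8.62) and over the dorsal hindbrain list 8.25 (7.56 to 7.7). In tumour 1, Hmgb2 was low at 6414 (9104 to 10950) and the mean 3' to 5' ratio high at 1.591 (1.332 to 1.392). Isl1 was 695.7 in tumour 5 and at most 14.1 in the other tumours, and Mycn was 8084 in tumour 3 (9816 to 10950). In tumour 4, Hoxb5 and Hoxc4 were 20.8 and 10.3, both near background. In DBS 2, Ccnd2 was 883.7 (1550 to 1694), E2f1 59.4 (13.7 to 14.5), Skor1 9496 (6707 to 7050) and Ttr 606.2 (14510 to 27660). Barhl1 was 151.5 in DBS 4 (83.8 to 87.8) and Mki67 706.1 in DBS 1 (967.7 to 1031).

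Probe sets with no single gene name, left out of every comparison, also held signal. Of 4266 tested, 143 were higher in tumours than in both normal tissues and 383 lower. The probe set farthest above both read 254.3 on average in tumours, with 7.53 in GNPC and 6.33 in DBS, and the next read 401.9 in tumours, with 20.7 and 13.6. In the other direction, the probe set farthest below both read 105.1 in tumours, with 2139 in GNPC and 6287 in DBS, and the next read 81.1, with 1144 and 1230.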

How the results depend on the processing

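The alternatives that left out tumour 2 with GNPC 1 or added the Y-linked covariate were chosen after seeing the data; the others were planned. No call of a named gene or of a list reversed, and calls of other genes were not checked for reversal. The medians of 4 lists that did not pass changed sign with arrays scaled to the same median. Wnt targets between tumours and GNPC went from -0.18 to 0.05, and oligodendrocytes between tumours and DBS from -0.09 to 0.02. Between GNPC and DBS, stem cell genes went from 0.09 to -0.02 and choroid plexus genes from 0.01 to -0.1. Counts of genes depended most on what was counted. Without the minimum fold they were 6061, 8642 and 5414 for tumours against GNPC, tumours against DBS and GNPC against DBS, and 2318 and 2653 genes lay above and below both normal tissues. Counting all probe sets gave 4727, 8850, 4529, 1194 and 2470. These follow from how the alternatives are built, a looser threshold and more items tested. Scaling to the same median raised the genes above both tissues from 663 to 1026, and a pseudocount at the median of all values lowered those below both from 1367 to 882; a larger pseudocount shrinks the changes of dim genes. All other settings stayed within 1.5 times the main counts. With 1 sample left out the counts ran from 2243 to 2658, 4362 to 4548, 2000 to 2304, 567 to 694 and 1223 to 1444. Without tumour 2 and GNPC 1 they were 2378, 4532, 2340, 617 and 1306, and with the Y-linked covariate 2599, 4459, 2152, 671 and 1348.

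The difference in similarity ran from 0.152 to 0.168 with 1 sample left out. It then had an exact permutation p of 0.1 without a DBS sample and 0.0667 without a GNPC sample, the smallest those designs allow. The position of the tumours, 1.15, was 1.21 with a 70th percentile filter, 1.18 without the marker lists, and 1.13 to 1.19 with 1 sample left out; the cause was not tested. Lists passing numbered 32 in all, 6 with an estimated correlation, 52 with directional fry, and 30 to 36 with 1 sample left out. The 3' to 5' difference between tumours and GNPC was 0.17 with Gapdh alone and no longer passed, and that between tumours and DBS was -0.51 with beta-actin alone and passed; the cause was not tested.

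Of 291 values of named genes, 244 kept their side of the threshold in every setting, 29 lost a call in some setting and 18 gained one. Of 75 list results, 63 kept their side in every setting other than the estimated correlation and fry. No paired analysis was possible because the labels give no replicate numbers. Dim probe sets limit the rest: below about 18 intensity units, log2 differences are compressed. Examples are the Hox genes and Prph in tumours, Lcn2 in GNPC, and Mndal and Mfap4 in DBS.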

Other observations

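The test of the marker gradient was chosen after the values were seen, as were the genes named here outside the rule for named genes.

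Single genes varied widely among the tumours. The transcription factor Pou4f1 was 2798.1, 2489.4 and 2584.2 in tumours 2, 5 and 6 and 100 to 778.5 in the others, and the rhombic lip factor Olig3 was 718.4, 1485.6 and 1556.2 in tumours 2, 3 and 4 and at most 88.9 in the others. Shox2, a homeobox gene of the brainstem and thalamus, was 1537.4 in tumour 3, near its level in DBS (482.9 to 1260.5), and at most 113.1 in the other tumours. Lhx9 was 403.4 in tumour 2 and at most 21.6 in the rest. Ifi202b, an interferon-inducible relative of Mndal, was 629.4 in tumour 2, where Mndal was lowest, and at most 78.8 in the other tumours.

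Markers of other tissues differed among samples of the same normal tissue. Ttr and Folr1, markers of the choroid plexus, were 26072.5 and 943.3 in GNPC 2, against 817.9 and 80.2 in GNPC 1 and 296 and 65.6 in GNPC 3. Ttr was 27338.4 in DBS 1, 14510.8 in DBS 3 and 27664.4 in DBS 4. The muscle genes Acta1, Mylpf and Tnnc2 were 1527.7, 631.8 and 573.3 in DBS 4, the highest of the 13 samples. In GNPC 1, Shox2 and Lhx9 were 415.5 and 519.4, against at most 14.3 and 62.3 in GNPC 2 and 3.

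Across the 6 tumours, the mean of the Purkinje cell list went with that of the differentiated granule neuron list (Pearson r 0.88, exact permutation p = 0.021, 0.063 after adjustment over 3 relations; Spearman rho 0.94, p = 0.017). Without the 2 tumours farthest from the median, r was 0.86. The lists share no gene, and after adjustment the relation did not pass. Neither list's relation with the mean of the oligodendrocyte list passed. For the Purkinje list r was 0.22 (exact permutation p = 0.66, 0.66 after adjustment) and rho 0.43 (p = 0.42). For the granule neuron list r was 0.42 (exact permutation p = 0.38, 0.57 after adjustment) and rho 0.66 (p = 0.18). Without the 2 farthest tumours r was 1 and -0.66. The oligodendrocyte gene Mobp did rank the 6 tumours in the same order as Gabra6, Cbln3, Pcp2 and Calb1. Mbp, Mag and Mog did not, with tumour 1 above tumours 3 to 6.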
